A study of Sus scrofa with 11 samples.

How the data were processed

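The samples were pieces of cortex of about 100 mg from 11 pigs, 1 array per animal, with 250 ng of total RNA labelled per array. The labels call the tissue frontal cortex in the titles and frontoparietal cortex in the extraction protocol. The labels name 2 randomised groups and count separate animals in each, 5 hyperglycemic and 6 normoglycemic, and groups were taken from the titles. The deposited values are on the log2 scale and were used as deposited. Affymetrix Expression Console, RMA and limma are named per the submitters' processing notes, without versions. RMA corrects the background, normalises arrays by quantiles and summarises probes into a log2 value. The genome build and annotation behind the array are not given in the sources used here, so no coordinates are printed. Signal compression at the low and high ends of an array makes folds there smaller than the change in RNA.

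Of 19124 transcript clusters 13680 were in the annotation table given with the array. There 13143 had 1 gene symbol, 537 had several and were named by none, and 5444 had none. This gave 12206 distinct genes, 1139 of them known only by a locus number. Symbols were updated through the Entrez ID for 7 clusters, and 12841 of 13010 such IDs were in the RefSeq gene table. For the 878 genes with more than 1 cluster the one with the highest mean over all arrays stood for the gene. In 477 cases a row of values repeated an earlier row on all 11 arrays, and all rows were kept. No value was filtered out, and columns without a sample numbered 0.

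Differences are hyperglycemic minus normoglycemic. Each transcript cluster was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, Benjamini-Hochberg over 19124, threshold 0.05), without covariates. The lists of genes, the main tests, the rule for named genes and most alternatives were set before the data were examined. Gene lists, 49 in all, covered metabolism, stress and injury, brain function and cell types, with 724 of 1114 entries measured. The 45 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with fry. Fry asks whether the genes of a list move one way on balance and does not set them against other genes. The mean of each list per animal was compared by an exact permutation test over all 462 splits, two-sided, whose smallest p is 0.0021645. Intervals of list means are 95% intervals from the spread between animals. The list of Y-linked and X-inactivation genes had 0 of 11 genes measured. The lists of complex I, ATP synthase, antioxidant genes, reactive astrocyte genes, ion pumps and lymphocytes differed in sign among mean, median and test, and none of them was called.

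Named genes were, by the rule, the 10 with the smallest unadjusted p in each direction where none passed, the 3 members with the smallest p of each list called by camera and 1 member of every other list, and 13 genes fixed by name. Other clusters of a named gene went in the same direction where there were any.

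The limma and camera steps were tested on simulated data with the real means and spread, 20 tables with 200 of 19124 clusters changed and noise independent between genes. At an adjusted p of 0.05, 77.1% of 1.5-fold, 92.2% of 2-fold and 98.4% of 3-fold changes were recovered, and tables without change gave 0 calls. A shift of 0.3 in the 12 glycolysis genes was called by camera in 20 of 20 tables. Noise shared between genes, which the real arrays hold, was not simulated. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

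The alternatives were a filter on the lowest 25% of signals, 1 cluster or the average per gene, quantile normalisation, centring on the array median, a prior with trend, array weights, a test without shared variance, other thresholds, the replicate number as a block, oligodendrocyte or erythroid marker means as covariates, and leaving out each animal. Keeping identical rows once and leaving out the 2 arrays least like the others were added after the data were seen. A covariate from Y-linked genes was not run, as none was measured, and the sex of the animals is not given in the sources used here.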

Results

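Gene expression was measured in the cerebral cortex of 11 young pigs of around 25 kg that had gone through an induced cardiac arrest at a raised or a normal blood glucose. Glucose and insulin were infused towards a target of 8.5 to 10 mM in the 5 hyperglycemic animals and 4 to 5.5 mM in the 6 normoglycemic animals. In all 11 animals ventricular fibrillation lasted 5 min, resuscitation 8 min and the observation period 180 min, so each comparison is between arrests at different glucose levels, with no animal without an arrest among those analysed here. Each animal gave a single array, with signals for 19124 transcript clusters on the log2 scale. The median signal of an array lay between 7.41 and 7.48, and pairs of arrays correlated at 0.984 to 0.995 across transcript clusters, which are not independent replicates. The median correlation was 0.990 within groups and 0.991 between groups. The first principal component held 19.5% of the variance and the second 17.1%, and neither separated the groups (exact permutation tests, two-sided, p = 0.329 and p = 0.626).

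The question of the comparison was whether cortical genes, those of metabolism above all, differed after arrest between the glucose levels. Markers of oligodendrocytes, the cells that make myelin, were lower in the hyperglycemic animals, in all 10 of those measured. CNP, a myelin enzyme, had a signal of 10.10 ± 0.37 (SD, n = 5) in hyperglycemic and 10.88 ± 0.28 (SD, n = 6) in normoglycemic animals, a fold of 0.581. In the other direction SPTLC3, a subunit of the enzyme that starts sphingolipid synthesis, had 7.17 ± 0.30 (SD, n = 5) against 6.60 ± 0.13 (SD, n = 6), a fold of 1.48. No single gene passed the test across the array. With limma, 0 of 19124 transcript clusters had an adjusted p under 0.05 or under 0.1, and the lowest adjusted p was 0.806. At an unadjusted p under 0.05 there were 1022 transcript clusters where chance alone gives 956.2, with 396 higher and 626 lower in the hyperglycemic group. A test of each transcript cluster on its own variance called 0 as well. With a difference of at least 1.5-fold added to the unadjusted threshold, 10 were higher and 73 lower. The median 95% confidence interval of a difference reached 0.20 to either side on the log2 scale, or 1.15-fold, and the number of arrays limits the precision. Groups without overlap were seen for 71 transcript clusters, 0.371% of them, where chance gives 0.433%.

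The 10 named genes with the smallest unadjusted p in each direction are given as genes that did not pass, with adjusted p of 0.806 or 0.845. Among the higher ones, CNIH3, an auxiliary subunit of AMPA-type glutamate receptors, differed by 0.40 ± 0.09 (SE) on the log2 scale. REEP1, a protein that shapes the endoplasmic reticulum of neurons, differed by 0.29 ± 0.09 (SE), and SACM1L, a phosphoinositide phosphatase, by 0.20 ± 0.06 (SE). BTG4 differed by 0.40, MIR335 by 0.37, ERICH3 by 0.35, WNT2 by 0.34, the mitochondrial ribosomal protein gene MRPL44 by 0.26 and MIR30D by 0.22. Among the lower ones, CLCA2 differed by -1.02 ± 0.20 (SE), ATP6V1C2, a subunit of the vacuolar proton pump, by -0.99 ± 0.22 (SE), and RNF220, a ubiquitin ligase, by -0.82 ± 0.19 (SE). CNP differed by -0.78, SLAIN1, which promotes microtubule growth, by -0.72, the unconventional myosin MYO1D by -0.56, and REEP3 by -0.51. FBXO32 differed by -0.48, AGPAT4, an acyltransferase of phospholipid synthesis, by -0.45, and MID1IP1, a regulator of fatty acid synthesis, by -0.33. With the mean of the oligodendrocyte markers as a covariate, the differences of the 10 lower genes lay between -0.37 and -0.11. Their median moved from -0.64 to -0.17, and 0 of them kept an unadjusted p under 0.05. CNP is itself 1 of the markers in that mean, so its own fall was built in. That mean also differed between the groups, so a smaller difference does not show what these genes depend on. The differences of the 10 higher genes lay between 0.13 and 0.47, with a median of 0.24 in place of 0.34. Of these higher genes 2, SPTLC3 and MIR30D, kept an unadjusted p under 0.05. CALB1, a calcium-binding protein of neurons, chosen after its values were seen, was the 1 transcript cluster at least 2-fold higher, at 8.10 ± 0.57 (SD, n = 5) against 7.06 ± 0.85 (SD, n = 6), with an adjusted p of 0.902 from limma. At least 2-fold lower were 7 transcript clusters.

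Metabolic genes as a whole showed no difference past the test between the glucose levels. Over the 231 measured of 360 genes fixed for glucose, energy and lipid metabolism, the mean signal was 9.32 ± 0.02 (SD, n = 5) in hyperglycemic and 9.32 ± 0.03 (SD, n = 6) in normoglycemic animals. The difference was 0.00188, with a 95% confidence interval of -0.033 to 0.0368 and an exact permutation p = 0.877. Of these genes 129 were higher and 102 lower. At an unadjusted p under 0.05 limma gave 12, or 5.19%, against 619 of the 11975 other genes, or 5.17% (Fisher's exact test, two-sided, p = 1, odds ratio 1.01, 95% confidence interval 0.509 to 1.80). The 7 higher ones were ATP5O, NDUFA5, SLC2A13, DLAT, MRPL44, PRPS2 and ME3, and the 5 lower ones ACSL1, MSMO1, NSDHL, SCD and PKLR. Among the metabolic genes 0 passed limma over all genes and 0 when adjusted over the list alone, where the lowest adjusted p was 0.639.

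**Figure D1:**
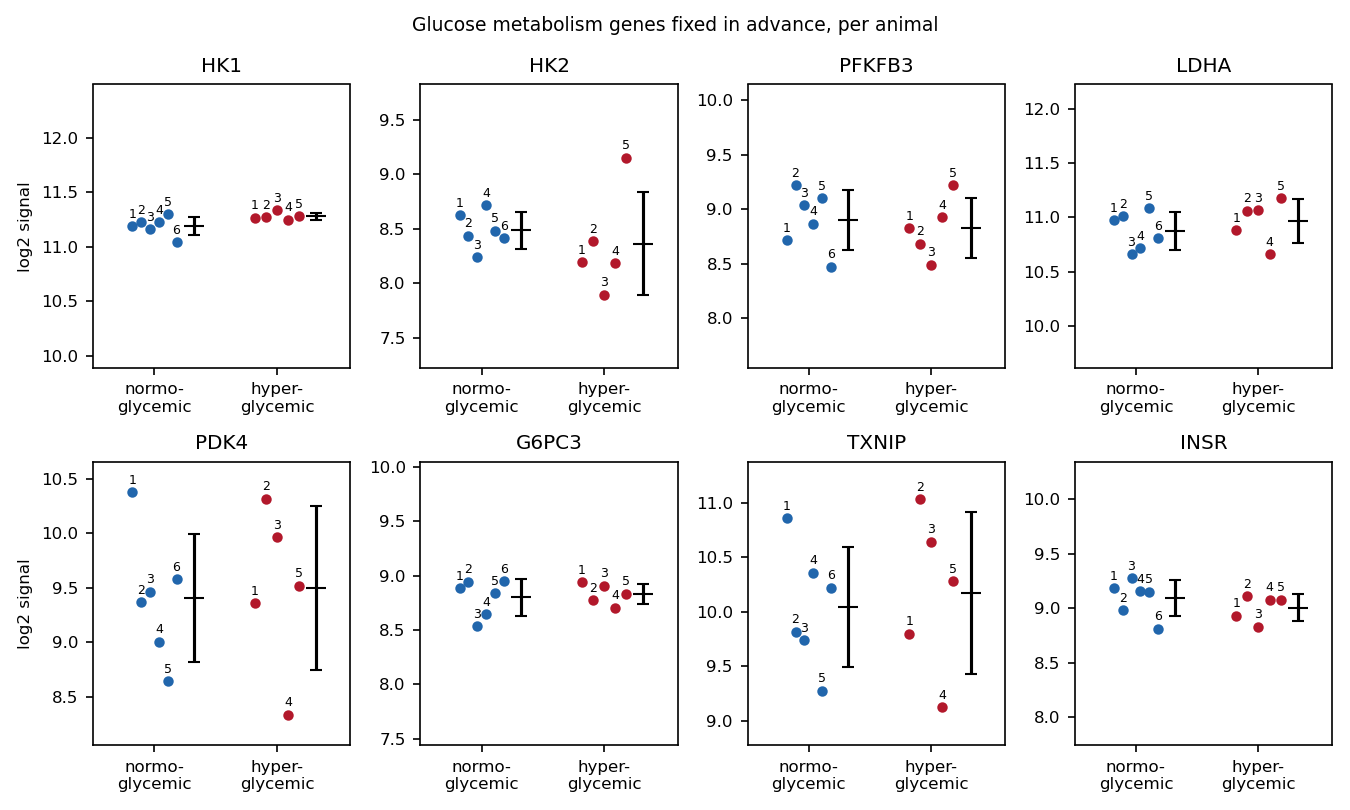
The log2 signal of 8 glucose metabolism genes fixed in advance is plotted for each animal, numbered by replicate, with normoglycemic animals in blue, hyperglycemic animals in red, and the mean and SD of each group as black bars; panels span equal ranges. HK1 varies little within groups, while TXNIP and PDK4 spread widely in both groups and their groups overlap.

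The genes of glucose handling fixed in advance did not pass the test. HK1, the main hexokinase of brain, was at 11.28 ± 0.03 (SD, n = 5) in hyperglycemic and 11.19 ± 0.09 (SD, n = 6) in normoglycemic animals, a difference of 0.09. HK2, an inducible hexokinase, differed by -0.12, LDHA, a lactate dehydrogenase subunit, by 0.09, and PFKFB3, an activator of glycolysis, by -0.07. G6PC3, a glucose-6-phosphatase, differed by 0.03, and INSR, the insulin receptor, by -0.09. TXNIP, which is induced by glucose through MondoA, was at 10.17 ± 0.74 (SD, n = 5) against 10.04 ± 0.55 (SD, n = 6), and PDK4, an inhibitor of pyruvate dehydrogenase, at 9.50 ± 0.75 (SD, n = 5) against 9.41 ± 0.59 (SD, n = 6). Without hyperglycemic 5, HK2 was at -0.32, PFKFB3 at -0.17 and LDHA at 0.04. With the oligodendrocyte covariate HK1 was at 0.00732, HK2 at -0.42, LDHA at -0.09, PFKFB3 at -0.18, G6PC3 at 0.13, INSR at -0.21, TXNIP at -0.24 and PDK4 at -0.03. With the erythroid covariate TXNIP was at 0.38, PDK4 at 0.33, G6PC3 at 0.08, INSR at -0.17, PFKFB3 at -0.17, HK2 at -0.06 and HK1 at 0.04. In limma, without these changes, adjusted p ran from 0.902 for HK1 to 0.986 for PDK4. SLC2A1, SLC2A3, HMOX1 and HSPA1A were also fixed in advance and had no transcript cluster of a single gene.

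By pathway, cholesterol and fatty acid synthesis was the lower metabolic group and lactate, pyruvate and ketone use the higher one. All 12 measured genes of cholesterol and fatty acid synthesis were lower in the hyperglycemic group, with a mean difference of -0.14 (camera adjusted p = 1.66e-05). The list had an adjusted p = 0.587 with an estimated correlation and an exact permutation p = 0.0216. With the oligodendrocyte marker mean as a covariate its difference was -0.000825 ± 0.0552 (SE). Examples were NSDHL at -0.29 and MSMO1 at -0.19, enzymes of sterol synthesis, and SCD, the stearoyl-CoA desaturase, at -0.17, and these 3 had an unadjusted p under 0.05. With that covariate they were at 0.02, -0.08 and -0.13. Of 13 genes for lactate, pyruvate and ketone transport and use 11 were higher, by 0.08 on average (camera adjusted p = 0.0457). That call has an adjusted p = 0.669 with an estimated correlation and an exact permutation p = 0.0823, and it ended on leaving out any of 7 animals, hyperglycemic 1, 2 or 4 or normoglycemic 1, 2, 5 or 6. With the oligodendrocyte marker mean as a covariate its difference was 0.04 and the call ended (camera adjusted p = 0.331), as it did with the erythroid covariate at 0.07 (0.164), quantile normalisation (0.0769), the average of a gene (0.0615), the lowest 25% of signals left out (0.0596), array weights (0.0565) and arrays centred on their median (0.0541). Among its members BDH1, a ketone body dehydrogenase, was at 0.19, PDK3 at 0.17 and DLAT, a subunit of pyruvate dehydrogenase, at 0.12.

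The other metabolic lists passed no test over all 11 animals. Glucose transporters and hexokinases differed by 0.07 over 8 genes (camera adjusted p = 0.291), with the myo-inositol transporter gene SLC2A13 at 0.30. Glycolysis differed by 0.01 over 12 genes (0.586), with PFKFB2 at 0.18, and gluconeogenesis and glycogen by 0.000951 over 17 (0.878), with GBE1, the glycogen branching enzyme, at 0.13. The pentose phosphate pathway differed by 0.06 over 6 (0.573), with PRPS2 at 0.33, and the tricarboxylic acid cycle by 0.05 over 13 (0.277), with the mitochondrial malic enzyme ME3 at 0.24. In the respiratory chain, complex I differed by -0.00885 over 31 genes (0.836), with NDUFA5 at 0.17, complexes III and IV by -0.07 over 7 (0.686), with COX6A1 at -0.08, and ATP synthase by -5.76e-05 over 11 (0.888), with ATP5O at 0.13. Transcripts of the mitochondrial genome differed by 0.02 over 8 (0.650), with ND1 at 0.04, and mitochondrial ribosomal proteins by 0.01 over 51 (0.586). Fatty acid oxidation differed by -0.02 over 18 (0.573), with ACSL1, an acyl-CoA synthetase, at -0.32. Targets of the glucose-sensing factors MondoA and ChREBP differed by -0.06 over 9 (0.291), with PKLR at -0.26. Without hyperglycemic 5 that list was at -0.11 and camera called it (adjusted p = 0.0363, exact permutation p = 0.167). Glucose transporters and hexokinases were at 0.03 without that animal and at -0.02 with the oligodendrocyte covariate, where SLC2A13 was at -0.06, PRPS2 at 0.06 and ACSL1 at 0.00437. With that covariate the MondoA and ChREBP list was at -0.16 ± 0.12 (SE). Without hyperglycemic 5, gluconeogenesis and glycogen was at -0.02, fatty acid oxidation at -0.03, complexes III and IV at -0.04 and insulin signalling at -0.00373. Insulin signalling and its targets differed by 0.00249 over 16 (0.888), with SESN1 at 0.16.

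Oligodendrocyte markers were lower together in the hyperglycemic animals. Their mean signal was 9.73 ± 0.43 (SD, n = 5) against 10.56 ± 0.36 (SD, n = 6), a difference of -0.84 with a 95% confidence interval of -1.38 to -0.30 and a fold of 0.559. All 10 measured markers were lower, each with an unadjusted p under 0.05, among them UGT8, which makes the galactolipids of myelin, at -0.91, MAG, a myelin adhesion protein, at -0.79, and CNP at -0.78. The list passed camera (adjusted p = 8.21e-17), and all 10 genes passed when adjusted over the list alone, the lowest adjusted p being 0.00462, while 0 passed over all genes. The list had an adjusted p = 0.560 with an estimated correlation, since the markers varied together between animals. The exact permutation test of its mean over the 462 splits of the animals gave p = 0.0152, and 0.244 after Benjamini-Hochberg adjustment over 45 lists. The groups overlapped, as hyperglycemic 1 at 10.19 and hyperglycemic 4 at 10.17 lay above normoglycemic 5 at 10.12. The list set for oligodendrocyte precursors had 4 measured genes, too few for camera. All were lower, by -0.44 on average (exact permutation p = 0.0108), and OLIG1, SOX10 and BCAS1 passed when adjusted over the list alone. OLIG1, a transcription factor of the lineage, was at -0.39, and at -0.06 with the oligodendrocyte marker mean as a covariate. Its difference is thus not shown to be separate from that of the oligodendrocyte list. A change of the precursors themselves is not shown by these 4 genes.

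**Figure D2:**
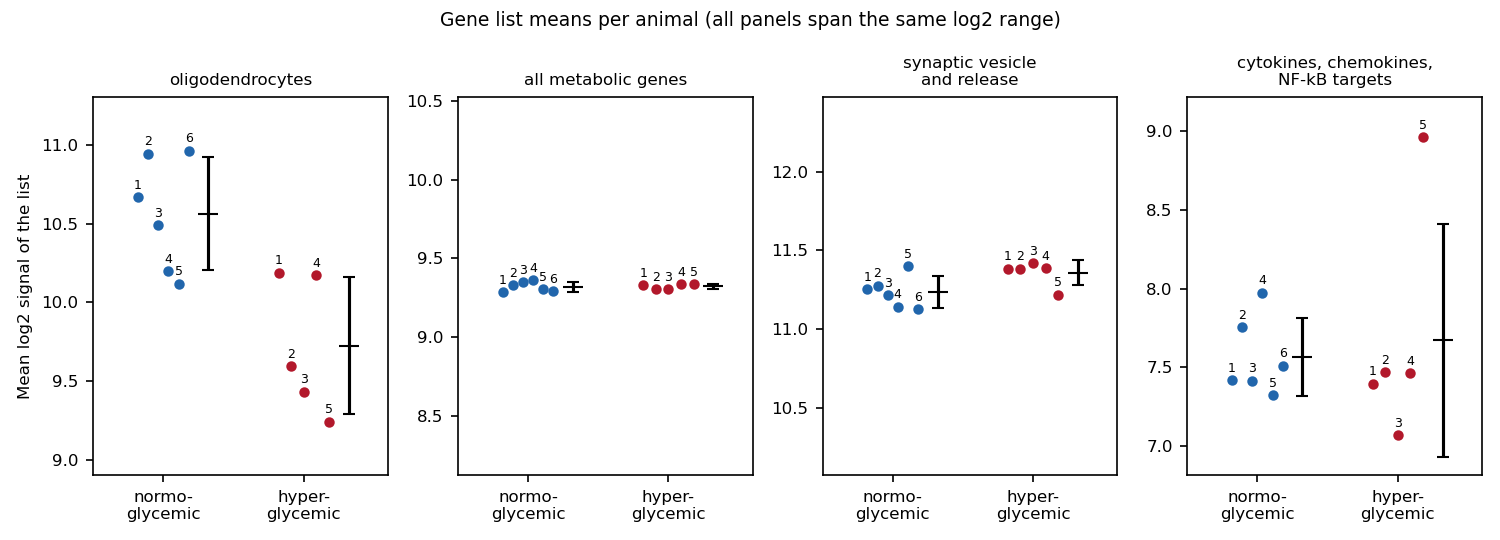
The mean log2 signal of 4 gene lists is plotted for each animal, numbered by replicate, with normoglycemic animals in blue, hyperglycemic animals in red, and the mean and SD of each group as black bars; all panels span equal log2 ranges. The oligodendrocyte means of the groups are 9.73 and 10.56, the metabolic means are both 9.32, and hyperglycemic 5 stands apart at 8.96 for the cytokine list.

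Several neuronal lists were slightly higher in the hyperglycemic animals. Glutamate receptors and transporters and ion pumps and voltage-gated channels, given with the other brain lists, hardly differed. Markers of inhibitory neurons differed by 0.20 on average, with 10 of 11 higher (camera adjusted p = 0.0186). The list had an adjusted p = 0.669 with an estimated correlation and an exact permutation p = 0.0130. Examples were CALB2 at 0.71 and the neuropeptide genes VIP at 0.42 and CCK at 0.26, of which VIP was at -0.08 and CCK at -0.11 with the oligodendrocyte marker mean as a covariate. GABA receptor and synthesis genes differed by 0.12, with all 8 measured of 20 genes higher (camera adjusted p = 0.00814). Among them were the receptor subunits GABBR2 at 0.18 and GABRB2 at 0.18 and ABAT, which breaks GABA down, at 0.15. That list had an adjusted p = 0.587 with an estimated correlation and an exact permutation p = 0.0173. Genes of synaptic vesicles and release differed by 0.12, with 14 of 16 higher (camera adjusted p = 9.65e-05), among them SYN1 at 0.24, SV2A at 0.21 and VAMP2 at 0.13. This list had an adjusted p = 0.669 with an estimated correlation and an exact permutation p = 0.0649. Excitatory neuron markers differed by 0.11 over 8 genes and did not pass (camera adjusted p = 0.0577), with CAMK2A at 0.11. Without hyperglycemic 5 that list was at 0.16 and was called (camera adjusted p = 0.0156, exact permutation p = 0.0429). Beside these groups, the oligodendrocyte mean was lower by the values above, and with it as a covariate the inhibitory list was at 0.08, the GABA list at 0.09 and the synaptic list at 0.13. That covariate ended the camera calls of the inhibitory and GABA lists, the erythroid covariate, with 0.15, 0.08 and 0.06 in that order, ended all 3, and leaving out normoglycemic 6 ended that of the inhibitory list (camera adjusted p = 0.0864).

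Proteasome genes leaned higher and cytosolic ribosomal protein genes lower by small amounts, with 0 members of either list at an unadjusted p under 0.05 in limma. Of 22 proteasome genes 18 were higher, by 0.05 on average (camera adjusted p = 0.0358), among them PSMA5 at 0.16, PSMD12 at 0.11 and PSMD1 at 0.11. It had an adjusted p = 0.669 with an estimated correlation and an exact permutation p = 0.0368, or 0.331 when adjusted over 45 lists. The call ended on leaving out any of 5 animals, hyperglycemic 1 or 4 or normoglycemic 1, 2 or 5. It also ended with quantile normalisation at 0.04 (camera adjusted p = 0.116), and with the erythroid covariate at 0.04 (0.0665) or the oligodendrocyte covariate at 0.05 (0.0584), so the difference itself moved little. Of 38 cytosolic ribosomal protein genes 31 were lower, by -0.08 on average (camera adjusted p = 1.66e-05), among them RPS16 at -0.25, RPLP0 at -0.19 and RPL36 at -0.17. It had an adjusted p = 0.737 with an estimated correlation and an exact permutation p = 0.186, and with the erythroid marker mean as a covariate its difference was -0.00665. Without normoglycemic 6 it was at -0.04 (camera adjusted p = 0.0155). Over all 45 lists tested, camera with its preset correlation called 5 higher and 3 lower. With an estimated correlation, with fry and with the adjusted exact test 0 lists passed, and 5 had an unadjusted exact permutation p under 0.05. Other brain lists passed no test: glutamate receptors and transporters differed by 0.01 (camera adjusted p = 0.799), with GRIA3 at 0.21, ion pumps and voltage-gated channels by -0.00497 (0.836), with the chloride cotransporter SLC12A2 at -0.54, or 0.03 with the oligodendrocyte covariate, and the circadian clock by -0.04 (0.586), with CLOCK at 0.11. Without hyperglycemic 5 the glutamate list was at 0.04 and the ion pump list at 0.02, and neither was called.

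**Figure D3:**
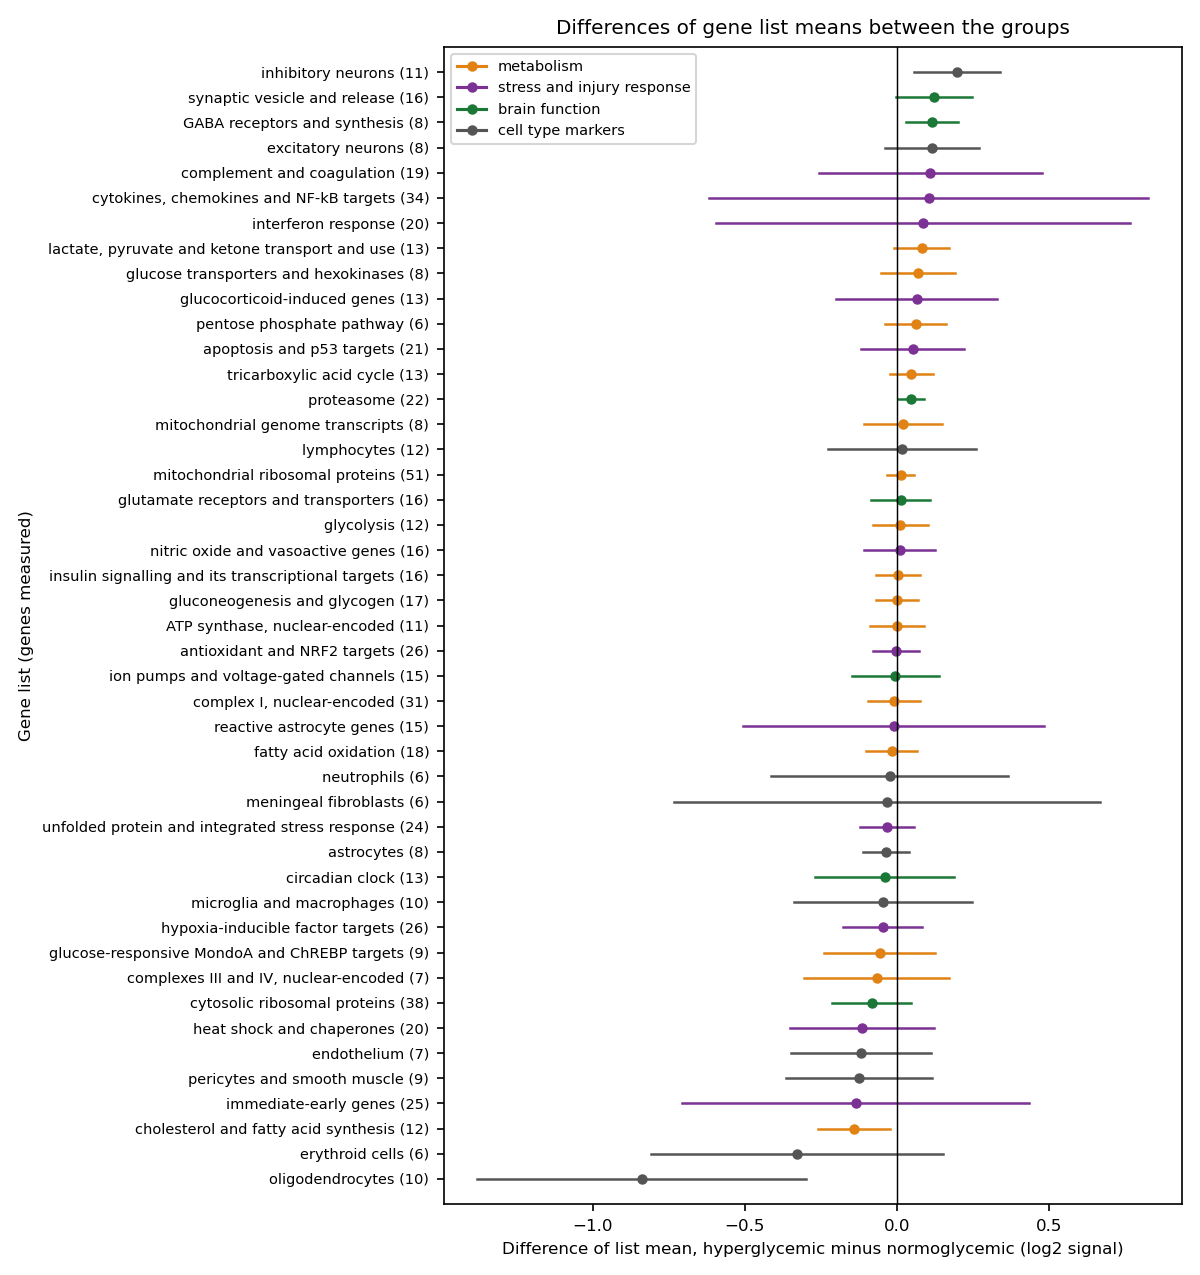
The difference of each gene list's mean log2 signal, hyperglycemic minus normoglycemic, is plotted as a point with its 95% confidence interval for the 45 lists with at least 5 measured genes, coloured by kind of list, with the number of genes in brackets. The oligodendrocyte list lies lowest at -0.84. Of the metabolic lists, cholesterol and fatty acid synthesis lies at -0.14 (-0.26 to -0.02), and the intervals of the others include 0.

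Markers of the remaining cell types did not pass the test over all 11 animals. Astrocyte markers differed by -0.04 (camera adjusted p = 0.576), with FGFR3 at -0.10, and microglia and macrophage markers by -0.05 (0.586), with P2RY12 at -0.22. Endothelial markers differed by -0.12 (0.0914), with KDR, a receptor for vascular endothelial growth factor, at -0.20, and those of pericytes and smooth muscle by -0.12 (0.139), with MCAM at -0.54. Erythroid markers differed by -0.33 (0.106), with the globin gene HBB at -0.81, neutrophil markers by -0.02 (0.794), with CXCR2 at -0.11, and lymphocyte markers by 0.02 (0.878), with CD4 at 0.11. Meningeal fibroblast markers differed by -0.03 (0.586), with DPT at -0.15. Choroid plexus and ependyma had 4 measured markers and differed by -0.05 (exact permutation p = 0.584), with CCDC153 at -0.18. Without hyperglycemic 5 camera called endothelial markers lower at -0.20 (adjusted p = 0.000934, exact permutation p = 0.0571), neutrophil markers at -0.19 (0.0177, exact 0.0571), those of pericytes and smooth muscle at -0.18 (0.0199, exact 0.143) and erythroid markers at -0.38 (0.0361, exact 0.152). Lymphocyte markers were at -0.08, microglia and macrophage markers at -0.11 and meningeal ones at -0.14 without it, and none of these was called. The genes CXCR2 and CD4 were at -0.27 and 0.07 without it. With the oligodendrocyte covariate pericytes and smooth muscle were at -0.36 ± 0.13 (SE), with MCAM at 0.06, endothelial markers at -0.20 ± 0.16 (SE), meningeal ones at -0.65 ± 0.42 (SE) and astrocyte markers at 0.02 ± 0.05 (SE). With the erythroid covariate CXCR2 was at 0.08.

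Genes of the response to arrest, injury and inflammation did not pass the test over all 11 animals. Immediate-early genes differed by -0.14 with 20 of 25 lower (camera adjusted p = 0.180). FOS, a transcription factor induced within minutes of a stimulus, was at 8.23 ± 0.97 (SD, n = 5) against 8.56 ± 0.57 (SD, n = 6), and DUSP4 at -0.55. Heat shock genes and chaperones differed by -0.11 (0.147), with the small heat shock protein gene CRYAB at -0.60, and targets of hypoxia-inducible factor by -0.05 (0.225), with NDRG1 at -0.38. The unfolded protein and integrated stress response differed by -0.03 (0.304), with CRELD2 at -0.13, and antioxidant genes by -0.00390 (0.787), with the ferritin gene FTL at -0.21. Metallothioneins and zinc handling had 4 measured genes and differed by 0.09 (exact permutation p = 0.604), with MTF1 at -0.13. Genes induced by glucocorticoids differed by 0.06 (0.787), with KLF9 at 0.39, and apoptosis and p53 genes by 0.05 (0.573), with XIAP, an inhibitor of caspases, at 0.13. Nitric oxide and vasoactive genes differed by 0.00992 (0.686), with NOS2 at 0.17. Without hyperglycemic 5 camera called heat shock genes lower at -0.16 (adjusted p = 0.0140, exact permutation p = 0.195), targets of hypoxia-inducible factor at -0.09 (0.0154, exact 0.114) and the unfolded protein response at -0.06 (0.0156, exact 0.0762). Without that animal FOS was at -0.66, and the glucocorticoid list at -0.01, apoptosis and p53 genes at -0.02 and nitric oxide genes at -0.03 had the opposite sign and were not called. With the oligodendrocyte covariate heat shock genes were at -0.00737, targets of hypoxia-inducible factor at -0.12 ± 0.09 (SE), antioxidant genes at -0.05 ± 0.05 (SE), CRYAB at -0.24, DUSP4 at -0.07 and XIAP at -0.00139.

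Inflammatory genes varied more between animals than between the glucose levels. Cytokines, chemokines and NF-kB targets differed by 0.11 with a 95% confidence interval of -0.62 to 0.83 (camera adjusted p = 0.544), with RELA at -0.18. Genes of the interferon response differed by 0.09 (0.586), with STAT2 at 0.12, complement and coagulation by 0.11 (0.304), with C1S at 0.33, and reactive astrocyte genes by -0.01 (0.794), with the ferroxidase gene CP at -0.71. One animal, hyperglycemic 5, held the high cytokine values, with a list mean of 8.96 against 7.07 to 7.97 in the 10 others. Without it the cytokine list was at -0.22 (camera adjusted p = 2.04e-05), the interferon list at -0.14 (0.0343), reactive astrocyte genes at -0.21 (0.0154) and the immediate-early list at -0.32 (2.02e-05), and camera called 15 lists lower in place of 3. The exact permutation p of these lists without it were 0.219, 0.610, 0.171 and 0.190. Complement and coagulation was at -0.03 without hyperglycemic 5, with C1S at 0.20, and was not called. With the oligodendrocyte covariate the cytokine list was at -0.28 ± 0.49 (SE), interferon at -0.34 ± 0.45 (SE), complement at -0.24 ± 0.21 (SE) and reactive astrocyte genes at -0.29 ± 0.33 (SE), with CP at 0.04 and C1S at -0.17.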

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

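The tests of leukocytes in the piece, of the amount of blood as the whole cause of the inflammatory values and of a fault of that array other than a shift were chosen after the result was seen, and the other tests here were set after the patterns were seen but before the values that decide them.

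For 91 named genes and 45 lists, 272 groups of animals were searched for a value far from the rest of its group, and 21 values (7.72%) stood apart where chance gives about 1 in 20 groups. Of these 9 were in hyperglycemic 5. In that animal the cytokine list was at 8.96 against 7.07 to 7.47 in its group, the interferon list at 9.44, neutrophil markers at 6.90 and lymphocyte markers at 6.67. CXCR2 was high there at 7.60, while the synaptic vesicle list at 11.22, excitatory neuron markers at 10.74, MSMO1 at 11.09 and WNT2 at 7.01 were low. In normoglycemic 6, CCK was low at 11.40 and GABRB2 at 11.83, and CXCR2 at 7.65 and the astrocyte list at 11.68 were high. In hyperglycemic 3 the circadian clock list was low at 9.26 against 9.71 to 9.78, as was MTF1 at 7.82, while ATP5O at 9.50 and PSMD1 at 10.86 were high. COX6A1 was low at 11.14 and BDH1 high at 7.45 in hyperglycemic 2. BDH1 at 7.57 and the GABA list at 10.96 were high in normoglycemic 5.

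Whether another grouping of the animals gives as much was counted over 100 splits, the real one included. As many transcript clusters at an unadjusted p under 0.05 as the real 1022 came from 40 splits, with 2104 as the highest of the others, so chance cannot be excluded. The real count of 0 past adjusted p 0.05 says nothing about chance, as all 100 splits reach it by necessity, with 2 as the highest other. At least the 8 lists that camera called came from 57 splits, with up to 23 in another, and at least the 12 metabolic genes from 28 splits, with up to 37, so chance cannot be excluded for these either.

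Oligodendrocyte markers were lower by -0.84 in the hyperglycemic group. For this list taken alone a chance split of the animals is argued against, as 7 of all 462 splits gave a difference as large (highest other 0.86), but it was the lowest of 45 lists and its exact p adjusted over them was 0.244. A single animal is argued against too, since leaving out any of the 11 kept at least 85.6% of the difference. A smaller share of white matter in the hyperglycemic pieces stays open and may account for it. Within groups the markers varied together with a mean pairwise correlation of 0.853. The share of lower genes outside the list that followed them was 30.5 times that of all other genes (157 of 352 against 173 of 11844). Both values could also arise if transcripts of 1 cell type rose and fell together, so they do not single out white matter. A loss of oligodendrocyte transcripts with the glucose level stays open as well, since these data hold no measure of how each piece was cut.

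With camera at its preset correlation the inhibitory neuron, GABA and synaptic vesicle lists were higher in the hyperglycemic group. Excitatory neuron markers did not pass (camera adjusted p = 0.0577). None of these lists passed with an estimated correlation, with fry or with the adjusted exact test, so chance cannot be excluded for them. Less white matter in the pieces could raise them, and the lists differ in how they follow the oligodendrocyte mean. With it as a covariate the synaptic vesicle list kept 103.7% of its difference and its camera call at the preset correlation (adjusted p = 0.00325). Its residual correlation to that mean was 0.0236 over the 11 animals. Without the covariate this list had an adjusted p = 0.669 from camera with an estimated correlation and an exact permutation p = 0.0649. With the covariate the remaining 0.13 ± 0.09 (SE) is too imprecise to decide. For this list white matter, an effect of glucose and chance thus cannot be told apart. The inhibitory neuron list kept 38.0%, at 0.08 ± 0.08 (SE) in place of 0.20 ± 0.06 (SE), and lost its call, with a residual correlation of -0.563, so a share of white matter stays open for it. The GABA list kept 78.9%, at 0.09 ± 0.06 (SE) in place of 0.12 ± 0.04 (SE), and lost its call as well, with a residual correlation of -0.185.

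Cytokine and chemokine genes were far higher in hyperglycemic 5, with the cytokine list mean 1.61 above the other hyperglycemic animals. The interferon list was 1.15 above them, at 9.44 against 7.94 to 9.23 in the 10 others, so another animal came near it. A shift of the whole array is argued against, as the cytokine list's own shift lay at percentile 100 of 10000 random lists of like expression. The largest shift of those lists was 0.29. That test was set for poor quality as well, but random lists do not hold genes that move together, so it does not exclude other faults of the array. This array was 1 of the 2 least like the others, with a mean correlation of 0.988 beside 0.987 for normoglycemic 6, and a fault of this kind stays open. The test of blood left in the piece that was set beforehand came out on the side of blood, since the erythroid mean of 6.08 lay above the range of 5.48 to 6.02 in its group, although by little. A second test, chosen after that value was seen, argues against the amount of blood as the whole cause. In it 2 hyperglycemic animals with a like erythroid mean had cytokine means at least 1.49 lower. Likewise 4 normoglycemic animals with a higher erythroid mean had cytokine means of at most 7.97, against 8.96 in hyperglycemic 5. By this mean, blood stays open only as part of the cause. The mean rests on 6 genes, and most of its spread comes from ALAS2 and HBB. In the 10 others these ranged from 5.68 to 9.81 and from 3.83 to 7.14. HBE1, HBM, HBZ and SLC4A1 varied far less, so the mean is a coarse measure of blood. More leukocytes stay open, as the neutrophil mean lay 0.34 above the highest of the 10 others. Of its members S100A12, S100A8 and S100A9 lay above all the others, while CXCR2, MMP9 and PGLYRP1 lay inside their ranges, so the excess is not one of all neutrophil markers. An inflammatory state of that animal itself was not tested.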

How the results depend on the processing

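Keeping identical rows once and leaving out the 2 arrays least like the others were chosen after the data were seen. Transcript clusters past adjusted p 0.05 stayed at 0 under all 24 settings run, leave-one-out fits included, with a lowest adjusted p of 0.411, while the threshold of an unadjusted p under 0.05 with 1.5-fold gave 83. Of 2177 alternative values of named genes 25 changed sign, in 17 of 91 genes, and none was called. The cause of the changes below was not tested, except that testing 1 cluster per gene leaves fewer to count. The number of arrays limits the precision of each value.

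Clusters higher at unadjusted p 0.05 (396) numbered 189 with the oligodendrocyte covariate and 199 with the erythroid covariate. Lower ones (626) numbered 209 and 407 with these, 374 with 1 cluster per gene and 372 with the average of a gene. Lists called higher (5) numbered 3 with quantile normalisation, 1 with the oligodendrocyte and 3 with the erythroid covariate, and 0 with an estimated correlation or fry. The erythroid covariate ended the camera calls of all 5 main lists, so the 3 called higher with it were other lists. Lists called lower (3) numbered 10 with the oligodendrocyte covariate, 13 without the 2 arrays least like the others, and 0 with an estimated correlation or fry. Metabolic genes at unadjusted p 0.05 (12) numbered 2 and 6 with the covariates. The oligodendrocyte list stayed at -0.84 with adjusted p = 0.560 for an estimated correlation and 0.283 for fry.

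No label ties same-numbered animals of the groups together. Their residual correlations were -0.06, -0.22, -0.13, -0.08 and -0.22, which cannot show whether the animals were handled in pairs. With the replicate block, clusters higher numbered 228, lists higher 2, lists lower 5 and metabolic genes 5, and 5 of the 8 called lists were kept.

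Without 1 animal, clusters higher ranged from 258 (without hyperglycemic 2) to 699 (without normoglycemic 5), with 261 without hyperglycemic 3, and lower ones from 482 to 753. Lists higher ranged from 3 (without hyperglycemic 1, normoglycemic 1, 2 or 6) to 7, and lists lower from 3 to 15 (without hyperglycemic 5), with 5 without normoglycemic 5 or 6. Metabolic genes ranged from 8 to 15, those past when adjusted over the list alone from 0 to 0, and the oligodendrocyte list from -0.95 to -0.72.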

Other observations

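The tests of meningeal markers were chosen after the spread of TXNIP between animals was seen.

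Among the genes of the inflammatory, complement, leukocyte, microglial, endothelial, erythroid and reactive astrocyte lists, those furthest above the other hyperglycemic animals in hyperglycemic 5 included chemokines and cytokines, chosen after their values were seen. CXCL8, which attracts neutrophils, was at 11.07 against 4.60 to 8.03 in the 10 others, IL6 at 10.02 against 5.38 to 6.91, and CXCL2 at 10.88 against 6.47 to 7.70. CCL2, which attracts monocytes, was at 11.84 against 6.43 to 10.14. Adhesion molecules of activated endothelium were high too, with SELE at 8.14 against 5.21 to 6.37 and ICAM1 at 9.81 against 7.50 to 8.41. The lymphocyte gene CD2 was at 8.40 against 6.28 to 7.41, the furthest of its list. PTPRC at 9.28, NKG7 at 7.80, CD3E at 7.06, LCK at 6.40 and CD4 at 6.03 also lay above the highest of the others, at 8.83, 7.28, 6.64, 6.27 and 5.87 in that order. CD3D at 6.21 lay inside 5.66 to 6.46 of the others, and CD3G, CD8A, CD79A, CD79B and GZMB also lay inside their ranges.

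TXNIP ranged over animals of both groups from 9.12 to 11.03, and the mean of 6 meningeal fibroblast markers from 8.03 to 9.41, or 2.60-fold. The hypothesis that TXNIP follows the share of meninges in the piece was tested on values with the group means removed. Pearson's r was 0.852 (permutation p = 0.0010, 0.00234 after Benjamini-Hochberg adjustment over 3 relations) and Spearman's rho 0.845 (permutation p = 0.00161) over 11 animals. Without the 2 animals farthest from the median r was 0.849. The TXNIP homologue ARRDC4, also a MondoA target, had r = 0.859 (permutation p = 0.00156) and rho = 0.809 (permutation p = 0.00395), with r = 0.764 without those 2. PDK4 had r = 0.577 (permutation p = 0.0668) and rho = 0.482 (permutation p = 0.139). In the 6 normoglycemic animals alone r for TXNIP was 0.780 (exact permutation p = 0.0708), and no value was computed within the 5 hyperglycemic animals. A share of meninges may thus add to the spread of TXNIP, as a hypothesis found and tested on the same animals. The adjustment does not cover the choice of the meningeal list among all lists. TXNIP and ARRDC4 are both MondoA targets, so their relations are not independent. With the meningeal mean as a covariate, the TXNIP difference between the groups was 0.17 with a 95% confidence interval of -0.33 to 0.67, against 0.13 (-0.75 to 1.01) without it.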
